A study of Arabidopsis thaliana with 36 samples.

How the data were processed

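Expression was measured on Affymetrix arrays in leaf material of 2-week-old Arabidopsis thaliana plants, with 36 arrays in 12 groups of 3 biological replicates. Per the labels, plants grew on soil under days of 11 h light and 13 h dark at 22 °C, were moved to 28 °C, and were sampled at noon before the move (0 h) and 24 h and 96 h after it. RNA was extracted from ground leaf with Trizol and a column, and was amplified into biotin-labelled sense-strand DNA with a whole-transcript kit. The 4 lines were pad4-1 (the control line of the design), siz1-2 pad4-1, sumo1-1 amiR-SUM2 pad4-1 (also spelled amiR-SUMO2 in the series text, called the SUMO line below) and eTK, a triple mutant of the heat shock factor genes HsfA1a, HsfA1b and HsfA1d whose label does not list pad4-1. The labels describe 27 arrays, all those of the lines carrying pad4-1, as a re-analysis of earlier samples and give no such remark for the 9 eTK arrays.

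The deposited values are log2 intensities, 1 value per probe set and array, which the authors made with the oligo package and RMA (background correction, quantile normalization and summary of probes). Neither version is stated, nor is it stated whether all arrays were processed together. The median log2 value per array lay between 3.42 and 3.74. No counts underlie array values, so the number of arrays limits the precision. The table held 38408 probe sets, of which the platform annotation gave 1 gene to 16746, several genes to 758 and no gene to 20904. Symbols and gene lengths came from the RefSeq annotation of assembly TAIR10.1, matched by locus for 16601 of the single-gene probe sets and not for 145. The authors name no genome build for the probe sets, so no coordinates are given. That annotation holds no gene descriptions, so genes without a symbol are given by locus.

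The groups, comparisons, tests, 23 gene lists, most alternatives and the rule for named genes were chosen before the data were examined. A linear model with 1 mean per group was fitted to all 36 arrays in limma 3.58.1 (R 4.3.3), with moderated variances (24 residual and 6.69 prior degrees of freedom). It was applied to the 17504 probe sets with at least 1 gene, called genes below although 165 genes had more than 1 probe set. The 26 comparisons were 24 h and 96 h against 0 h in each line, each other line against pad4-1 at each time, the SUMO line against siz1-2 pad4-1 at each time, and the difference between each line's response and that of pad4-1 (the interaction). Tests were two-sided. P values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Replicate numbers gave little sign of pairing: residuals of the same number correlated at a mean of 0.0179, against -0.00891 for other numbers. In 7 of 60 same-number pairs of compared groups the correlation was over 0.1. No pairing entered the model, but whether equal numbers mark material grown together is not known.

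Named genes were the called single-gene probe sets with the highest and the lowest log2 difference and no overlap between the arrays of both groups (for interactions, called ones), the top 6 each way in the main comparisons and the top 2 in the others, printed from the top. Up to 4 called members of each described list were named too, and the targeted genes. Genes picked otherwise are marked as chosen after their values were seen. Values are means ± SD of log2 values, differences carry a standard error (SE), and each group has n = 3.

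The annotation named 54 of the 374 genes in the fixed lists, so 4 lists had the 5 measured members required for a test: heat shock proteins and heat-induced regulators, endoplasmic reticulum (ER) folding, thermomorphogenesis and auxin growth, and cold and osmotic response. They were tested with camera (limma, preset correlation 0.01, adjusted over the lists of a comparison) and again with an estimated correlation. The other lists were described by member: 15 had 1 to 4 measured members, and 4 (camalexin and indole glucosinolate, floral organ identity, jasmonate synthesis and response, and phosphate starvation) had none. Of the targeted genes only SIZ1 was named by the annotation; PAD4, SUM1, SUM2, HSFA1A, HSFA1B and HSFA1D were not analysed here. After the annotation was seen, and before any difference was computed, 33 families of genes sharing a symbol stem were added. Lists of ribosome biogenesis, ER body and iron deficiency genes were added after leading genes had been seen.

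The test was tried on simulated data of the same size, with 200 of 17504 genes changed. For a single difference it recovered 78.3% of genes changed 2-fold and 22.7% of those changed 1.5-fold (24 h against 0 h in pad4-1), and for an interaction 37.7% and 4.35% (siz1-2 pad4-1 at 96 h). The likeness of both SUMO-deficient lines was the correlation across genes of their differences from pad4-1, set beside a simulated value for unchanged groups sharing the same control arrays. The simulated noise was independent between genes. Alternatives were a variance trend with robust fitting, no dim probe sets (lowest 25%), the compared groups' arrays alone, no eTK arrays, replicate number as a block, quantile normalization, median centring, array weights, all probe sets, all probe sets of each list gene, and each array left out in turn. Removing each array's trend on gene length (lowess on log10 length) was added after the arrays were seen to differ in it. Its base, a fit on only the probe sets with a gene length, was not planned before either. Figures were drawn with matplotlib 3.10.9. The 20904 probe sets without a gene were left out of the comparisons because they cannot be named.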

Results

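Leaf transcripts of 4 Arabidopsis lines were measured on 36 arrays before and after a move from 22 °C to 28 °C, a warm ambient temperature. The lines were pad4-1, siz1-2 pad4-1 (mutated in the SUMO ligase SIZ1), sumo1-1 amiR-SUM2 pad4-1 (depleted of the modifier SUMO, the SUMO line below) and eTK, which lacks the heat shock factors HsfA1a, HsfA1b and HsfA1d. Each line was sampled at 0 h, 24 h and 96 h with 3 arrays per group. All 0 h arrays are from 22 °C and all later ones from 28 °C, so a response below is to warmth and to 1 or 4 days of further growth, which cannot be told apart. Log2 intensities of arrays of 1 group correlated at 0.969 to 0.992. The first principal component (46.1% of the variance) set the eTK arrays of 96 h apart from all others. The second (16.7%) followed gene length, with a Spearman correlation of 0.591 between loading and length across the 8217 brighter single-gene probe sets. Genes are not independent replicates. The plot of this length trend shows that it differed between groups and, within some groups, between replicates. The Spearman correlation of each difference with length is therefore given beside the counts, across these brighter probe sets only. Over all 16601 probe sets with a length it was weaker in most comparisons, such as -0.232 in place of -0.348 in pad4-1 at 24 h. In some it was stronger, such as 0.187 in place of 0.0822 for the siz1-2 pad4-1 interaction at 96 h. For the SUMO line against pad4-1 at 96 h the sign changed (0.0506 in place of -0.0299).

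**Figure D1:**
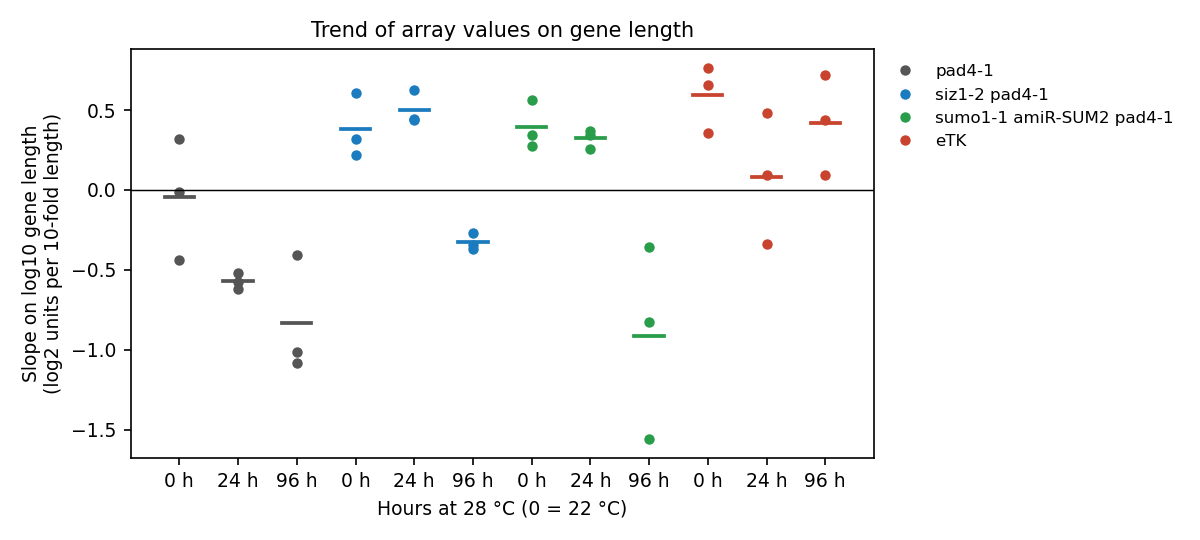
Slope of each array's log2 deviation from the mean of all arrays on log10 gene length (y axis, log2 units per 10-fold length), for the 12 groups of 3 arrays (x axis). Slopes were fitted across the 8217 brighter single-gene probe sets. Points are arrays and bars are group means. The mean slope fell from -0.04 at 0 h to -0.83 at 96 h in pad4-1, was 0.50 at 24 h in siz1-2 pad4-1, and spread from -1.56 to -0.35 in the SUMO line at 96 h.

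The pad4-1 response at 24 h asked what changed in the control line after the move. The locus AT1G62510 rose most, from 6.56 ± 0.36 to 9.10 ± 0.14 (SD, n = 3; log2 difference 2.55, SE 0.189, limma adjusted p = 3.46e-10). AT5G26270 rose by 2.39, AT5G57785 by 1.82 and the starch-related orphan gene QQS (AT3G30720) by 1.78. QQS was not called without the 0 h replicate 2 (1.07, adjusted p = 0.0814), and fitted on the 6 arrays alone neither QQS (adjusted p = 0.0936) nor AT5G26270 (adjusted p = 0.0525) was called. AT3G16530 fell most, with a log2 difference of -3.55 (11.7-fold lower; SE 0.383, adjusted p = 4.50e-07), followed by AT5G57760 at -2.91, the plant defensin gene PDF1.2 (AT5G44420), a marker of jasmonate and ethylene defence, at -2.57, and the organ growth gene ARL (AT2G44080) at -2.42. In all, 523 genes were higher and 630 lower, of which 102 and 196 by at least 2-fold. Thermomorphogenesis genes, which drive growth in warmth, moved both ways: the expansin EXPA8 (AT2G40610) rose by 0.87, while ARL and the light and temperature factor PIF7 (AT5G61270, -0.90) fell, and YUC2 and IAA29 were not called (camera adjusted p = 0.604; adjusted over the list alone also 1 higher and 2 lower). None of the 12 measured heat shock genes was called, over all genes or adjusted over the list alone (camera adjusted p = 0.604); HOP3 (AT4G12400) differed most, by 0.76. Among 5 ER folding genes the chaperone ERDJ3B (AT3G62600) rose by 0.44 (camera adjusted p = 0.631), and none of 6 cold response genes was called (0.722), with COR15B (AT2G42530) at -0.49. The log2 difference correlated with gene length at -0.348, and the count fell from 1153 to 584 without the 0 h replicate 1 and to 690 without the 0 h replicate 3.

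After 96 h in pad4-1 the anthocyanin enzyme DFR (AT5G42800) fell from 7.46 ± 0.54 to 2.49 ± 0.28 (log2 difference -4.97, SE 0.292, limma adjusted p = 3.26e-13, n = 3). AT4G22490 fell from 6.24 ± 0.05 to 1.15 ± 0.17, the lowest part of the array's range (-5.09, adjusted p = 1.14e-18), and the nearby, near-identical loci AT4G22485 and AT4G22520 followed at -3.94 and -3.91. AT3G44970 lay at -3.95 and AT4G29030 at -3.87. The iron deficiency peptide gene IMA1 (AT1G47400) rose from 4.12 ± 1.13 to 7.13 ± 0.53 (3.01, SE 0.411, adjusted p = 1.19e-05), beside AT3G22235 at 3.22, AT2G14247 at 2.78 and AT1G13609 at 2.76. In all, 800 genes were higher and 996 lower (140 and 316 by at least 2-fold, or 94 and 189 with the gene length trend removed). With each array centred on its median the split turned to 1092 higher and 864 lower. Of the cold response genes 3 of 6 rose, COR15A (AT2G42540) by 1.02, COR15B by 0.83 and KIN2 (AT5G15970) by 0.76 (camera adjusted p = 0.309; 3 adjusted over the list alone). EXPA8 rose by 1.25 and PIF7 lay at -0.93, as called members of 5 thermomorphogenesis genes (camera adjusted p = 0.309; 2 higher and 1 lower adjusted over the list alone). The small heat shock protein gene HSP23.5-MITO (AT5G51440) rose by 0.74, the 1 called member of 12 (camera adjusted p = 0.819; 1 adjusted over the list alone), and no ER folding gene was called (0.819), with BIP1 (AT5G28540) at -0.37. The difference correlated with gene length at -0.489. The count of 1796 fell to 627 without the 96 h replicate 3, 649 without the 0 h replicate 1, 994 without the 96 h replicate 1 and 1007 without the 0 h replicate 3, and rose to 2708 without the 96 h replicate 2. It fell furthest when limma was fitted on only the arrays of the groups compared, as given below.

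**Figure D2:**
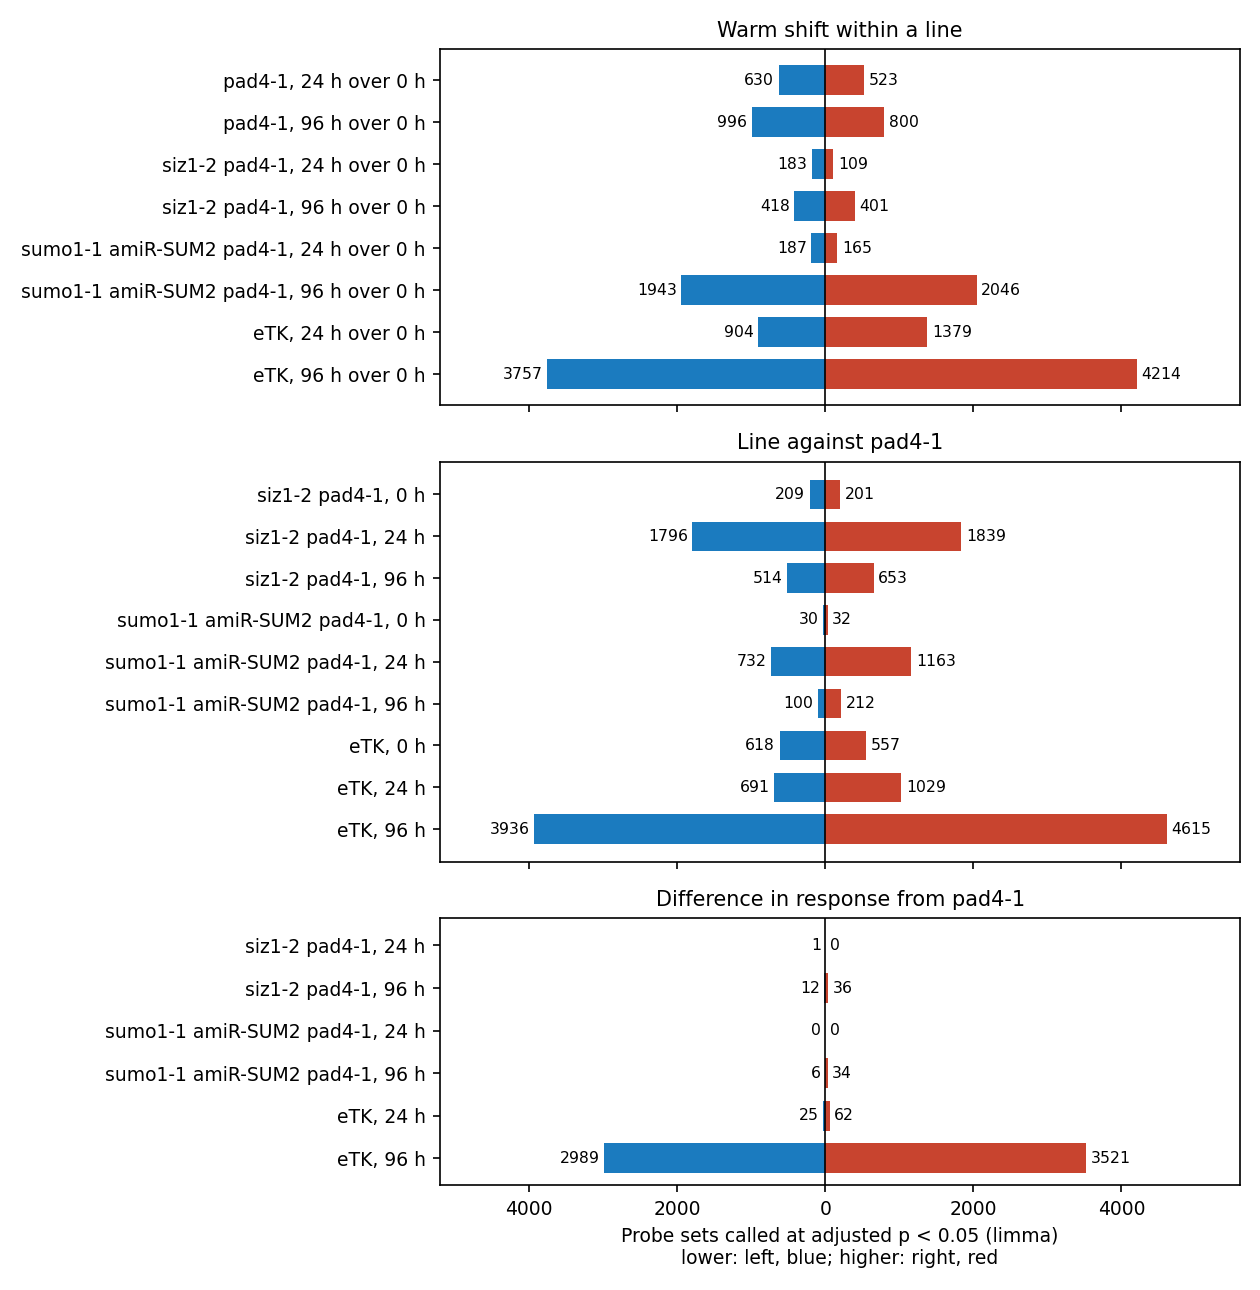
Genes called (limma, adjusted p under 0.05) as higher (right of 0) and lower (left of 0) in each comparison drawn (rows), as bars of counts. The bars for eTK at 96 h are the longest, with 4615 genes higher and 3936 lower than in pad4-1 and 4214 higher and 3757 lower than at 0 h, and those for the 24 h interactions of both SUMO-deficient lines hold 1 gene and none.

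The siz1-2 pad4-1 response was measured against the line's own 0 h arrays. At 24 h the calmodulin-like gene CML41 (AT3G50770) rose from 2.91 ± 0.95 to 5.11 ± 0.68 (SE of the difference 0.528, limma adjusted p = 0.0244, n = 3) and AT4G17470 by 1.87. The call of CML41 was lost when any 1 of 4 of its 6 arrays was left out (adjusted p up to 0.179). That of AT4G17470 was lost without either of 2 arrays (adjusted p up to 0.103). PDF1.2 fell from 6.12 ± 0.56 to 2.73 ± 0.16 (-3.39, adjusted p = 5.72e-05) and AT5G57760 lay at -2.56. At 96 h AT4G19430 rose by 2.61 and IMA1 by 2.50, and AT4G18250 (-2.29) and AT4G22485 (-2.15) fell most. At 24 h, 109 genes were higher and 183 lower, and at 96 h 401 and 418. ER folding genes shifted upward at 24 h (camera adjusted p = 0.0168; 0.0258 with an estimated correlation), with the ER chaperone BIP1 (1.07) as the 1 called member of 5. Thermomorphogenesis genes shifted downward (same adjusted p values), with ARL (-1.86) as the 1 called member. The list mean was -0.46 and its median -0.19, so ARL weighed heavily in that shift. The co-chaperone gene ROF2 (AT5G48570) rose by 1.36 among 12 heat shock genes (camera adjusted p = 0.112; 3 higher adjusted over the list alone). No cold gene was called at 24 h (0.534; 2 higher adjusted over the list alone), with KIN2 at 0.56. At 96 h cold response genes shifted upward (camera adjusted p = 0.0101), with COR15A (1.28) and KIN2 (0.88) called and 3 adjusted over the list alone, but the adjusted p = 0.103 with an estimated correlation. The other lists gave camera adjusted p values of 0.501 (heat shock, HSP23.5-MITO called at 0.71), 0.811 (ER folding, CRT1b (AT1G09210) at -0.28) and 0.811 (thermomorphogenesis, PIF7 called at -0.91; 1 higher and 1 lower adjusted over the list alone) at 96 h. The difference correlated with gene length at 0.129 and -0.481. The 24 h count of 292 fell to 162, 145 and 139 without the 0 h replicates 1, 2 and 3 and to 135, 136 and 165 without the 24 h replicates 1, 2 and 3; the 96 h count of 819 fell to 216 and 446 without the 0 h replicates 1 and 2 and to 395, 389 and 340 without the 96 h replicates 1, 2 and 3.

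In the SUMO line CML41 rose from 2.15 ± 0.23 to 4.82 ± 0.57 at 24 h (2.68, SE 0.528, limma adjusted p = 0.00365, n = 3) and stood at 5.09 ± 0.48 at 96 h. AT1G62510 rose by 2.15 at 24 h. The defensin genes PDF1.2b (AT2G26020) and PDF1.2 lay at -3.34 and -3.25 at 24 h; they are near-identical copies, and whether their probes separate them is not known. The call of PDF1.2b was lost when any 1 of 4 of its 6 arrays was left out (adjusted p up to 0.141). At 96 h IMA1 rose by 2.44, and AT4G22485 (-3.64) and AT4G05631 (-2.90) fell. Heat shock genes shifted upward at 24 h (camera adjusted p = 4.03e-04; 0.00454 with an estimated correlation), with ROF2 (1.89), HOP3 (1.28) and HSP23.5-MITO (1.03) called, and 4 adjusted over the list alone. ER folding genes also shifted upward (0.00766; ERDJ3B called at 0.57), thermomorphogenesis genes downward (0.0120; ARL called at -1.98) and cold genes downward (1.77e-04; COR15B at -1.51 and COR15A at -1.21 called, 3 adjusted over the list alone). These calls kept an adjusted p under 0.05 with an estimated correlation. ARL, the only called thermomorphogenesis gene, weighed heavily in the shift of its list, so that shift does not speak for the other members. At 96 h no list passed: camera adjusted p = 0.753 for heat shock (HSP15.7 (AT5G37670), at 1.03, and HSP23.5-MITO at 0.94 called) and 0.893 for ER folding (BZIP60 called at 0.65), thermomorphogenesis (PIF7 at -1.37 and EXPA8 at 0.98 called; 2 higher and 1 lower adjusted over the list alone) and cold (KIN2 at 0.89 and COR47 (AT1G20440) at -0.49 called; 2 higher and 2 lower adjusted over the list alone). In all, 165 genes were higher and 187 lower at 24 h (122 and 238 with each array centred), and 2046 and 1943 at 96 h. The difference correlated with gene length at -0.0722 and -0.585. The 24 h count of 352 fell to 194, 167 and 209 without the 0 h replicates 1, 2 and 3 and to 173, 187 and 194 without the 24 h replicates 1, 2 and 3; the 96 h count of 3989 fell to 1937 without the 96 h replicate 2.

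The eTK response asked how leaves lacking 3 heat shock factors change after the move. At 24 h DFR fell from 7.01 ± 0.48 to 3.90 ± 0.06 (-3.11, SE 0.292, limma adjusted p = 2.03e-08, n = 3), AT3G44970 (-3.02) and AT5G57760 (-2.54) fell too, while AT1G44130 (3.06), AT5G26690 (2.73), CML41 (2.65) and the expansin-like gene EXLA1 (AT3G45970, 2.27) rose. In all, 1379 genes were higher and 904 lower at 24 h. No heat shock gene was called at 24 h, also adjusted over the list alone (camera adjusted p = 0.239), with ROF2 at -0.75. The ER stress factor BZIP60 (AT1G42990, 0.91) and ERDJ3B (0.71) rose (list 0.0696), ARL (-1.14) and PIF7 (-1.11) fell (0.0696), and the cold genes KIN2 (0.91) and COR47 (0.79) rose (0.239); adjusted over the list alone the counts were the same. The difference correlated with gene length at -0.286, and the count of 2283 fell to 1267 without the 24 h replicate 3.

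At 96 h 7971 of 17504 genes (45.5%) were called in eTK, 4214 higher and 3757 lower, with 2564 and 2189 of them at least 2-fold apart. AT5G38910 rose from 1.37 ± 0.10 to 10.96 ± 0.16 (9.59, SE 0.330, limma adjusted p = 4.06e-21, n = 3) and the osmotin gene OSM34 (AT4G11650), a stress and defence protein, from 2.06 ± 0.32 to 11.12 ± 0.28. AT3G02480 (8.69), AT1G05340 (7.77) and AT5G55150 (7.63) followed. The lowest were AT3G16670 (-6.31), AT5G48490 (-5.64), AT1G66100 (-5.63) and AT5G57760 (-5.39). Of the 36 genes in the salicylic acid immunity list only 3 were measured, too few to speak for the list. All 3 rose: UGT76B1 (AT3G11340) by 6.04, the glutaredoxin GRX480 (AT1G28480) by 4.66 and SAG101 (AT5G14930) by 0.59. The senescence gene SAG29 (AT5G13170) rose by 5.79. Heat shock genes shifted upward (camera adjusted p = 0.0131; 0.0226 with an estimated correlation), with 6 of 12 higher, among them HSP23.5-MITO (3.78) and HSP17.8 (AT1G07400, 3.51), and ROF2 lower (-1.20). ER folding genes shifted upward (0.0117; 0.0194), with BZIP60 (3.72), BZIP28 (AT3G10800, 1.79), ERDJ3B (1.44) and BIP1 (0.82) called among 5. Thermomorphogenesis genes shifted downward (0.0117; 0.0194): EXPA8 (-4.55), PIF7 (-4.10), the auxin response gene IAA29 (AT4G32280, -3.01) and the auxin synthesis gene YUC2 (AT4G13260, -1.36) fell, while ARL rose by 2.71. Cold genes went both ways, with COR47 (1.67) and KIN1 (AT5G15960, 0.83) higher and COR15B (-1.42), COR15A (-1.14) and KIN2 lower (camera adjusted p = 0.765). Adjusted over the list alone, the counts of these 4 lists were the same. The difference correlated with gene length at -0.0325.

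**Figure D3:**
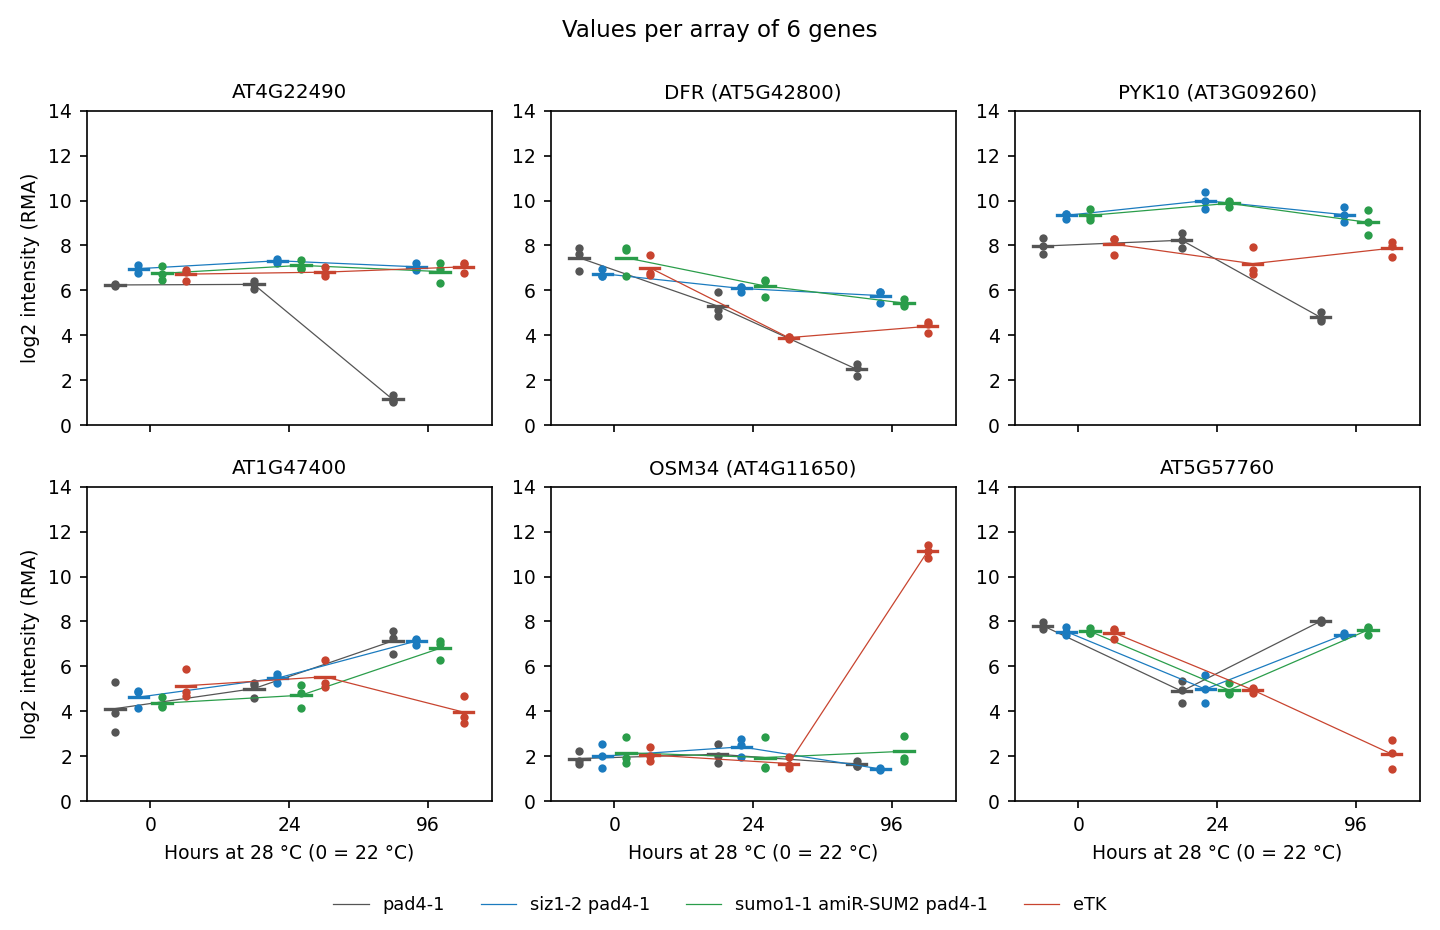
Log2 intensity (y axis) of 6 genes in the 12 groups (x axis), with a point per array and a bar at each group mean. AT4G22490 lay between 1.03 and 1.34 in pad4-1 at 96 h and above 6 in all other arrays, and OSM34 lay between 10.8 and 11.4 in eTK at 96 h.

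The siz1-2 pad4-1 line was compared with pad4-1 to see what loss of the SUMO ligase changes at each temperature. At 0 h AT2G11405 was at 5.24 ± 0.34 against 1.33 ± 0.11 (3.91, SE 0.155, limma adjusted p = 7.72e-18, n = 3), and AT1G27020 (2.73), AT2G32550 (2.39), AT5G46500 (2.28) and NAI2 (AT3G15950, 2.25), a gene of the ER bodies that store defence enzymes, were higher too. AT3G56210 (-3.86, 1 of 2 probe sets of the gene), QQS (-2.57) and AT2G34655 (-2.26) were lower. At 24 h AT2G11405 (3.88) and AT3G16530 (3.78) were highest and AT3G56210 (-4.98) and AT2G34655 (-3.86) lowest. At 96 h AT4G22490 stood at 7.05 ± 0.17 against 1.15 ± 0.17 (5.90, adjusted p = 1.47e-20), NAI2 at 4.82 above pad4-1, the ER body beta-glucosidase PYK10 (AT3G09260) at 4.57 and AT4G29030 at 3.90. AT3G56210 (-6.02), AT2G34655 (-3.90), AT5G26270 (-3.67) and QQS (-3.61) were lower. Cold response genes lay lower at 0 h (camera adjusted p = 7.83e-05; 0.0103 with an estimated correlation), with COR15A (-1.71) and COR15B (-0.81) called and 3 of 6 adjusted over the list alone. The same 2 genes were called at 24 h (-1.64 and -0.76; list 0.0407, but adjusted p = 0.160 with an estimated correlation) and at 96 h (-1.45 and -1.11; 0.0345, but adjusted p = 0.150), each time with 3 lower adjusted over the list alone. ER folding genes gave 0.0702 at 0 h (CRT1b at 0.44; 1 higher adjusted over the list alone), 0.0407 upward at 24 h (0.0807 with an estimated correlation), with BIP1 and CRT1b (1.05) higher and BZIP60 (-0.69) lower (3 higher and 1 lower adjusted over the list alone), and 0.136 at 96 h (BIP1 at 0.55; 3 higher adjusted over the list alone). No heat shock gene was called, also adjusted over the list alone (0.731, 0.987 and 0.752), with HSP17.6A-CI (AT1G59860, -0.42), HSP15.7 (-0.75) and HSP17.8 (0.60) differing most at the 3 times. Thermomorphogenesis genes gave 0.731, 0.987 and 0.233, with PIF7 (1.15) higher and IAA29 (-1.52) and EXPA8 (-0.55) lower at 24 h, and EXPA8 (-0.63) lower at 96 h; adjusted over the list alone, 2 were higher and 2 lower at 24 h and 2 lower at 96 h.

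In these comparisons of siz1-2 pad4-1 and pad4-1, 201 genes were higher and 209 lower at 0 h, 1839 and 1796 at 24 h, and 653 and 514 at 96 h, and 70 were higher and 80 lower at all 3 times. With each array centred on its median, 24 h gave 1558 higher and 2755 lower and 96 h 502 and 1241, and the median over all genes at 96 h moved from -0.0650 to -0.178. The differences correlated with gene length at 0.366, 0.502 and 0.393. The count of 410 at 0 h became 669, 170 and 193 without the pad4-1 replicates 1, 2 and 3 and 173 and 218 without the siz1-2 pad4-1 replicates 1 and 2. That of 3635 at 24 h fell to 2341 without the siz1-2 pad4-1 replicate 1. That of 1167 at 96 h became 669, 2173 and 481 without the pad4-1 replicates 1, 2 and 3, and 616, 605 and 703 without the siz1-2 pad4-1 replicates 1, 2 and 3.

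In the SUMO line at 0 h AT3G29639 stood at 9.66 ± 0.19 against 5.21 ± 0.17 in pad4-1 (4.45, SE 0.192, limma adjusted p = 9.74e-17, n = 3), with AT1G27020 (2.11) and NAI2 (1.63) higher, and AT3G56210 (-4.39), AT2G34655 (-2.54) and AT1G47740 (-2.16) lower. The call of NAI2 was lost when any 1 of 4 of the 6 arrays was left out (1.11 to 1.69, adjusted p up to 0.241). At 24 h AT3G29639 (3.71) and NAI2 (3.05) were highest and AT3G56210 (-5.51) and AT2G34655 (-3.95) lowest. At 96 h AT4G22490 (5.69, adjusted p = 4.35e-20), AT3G29639 (4.83), PYK10 (4.23), NAI2 (3.91) and AT4G29030 (3.85) were higher, and AT3G56210 (-5.37), AT2G34655 (-3.57) and AT5G26270 (-3.39) lower. ER folding genes shifted upward at 24 h (camera adjusted p = 0.0228; 0.0650 with an estimated correlation), with BIP1 (1.08) and CRT1b (0.81) called and 3 higher and 1 lower adjusted over the list alone. Cold genes shifted downward at 24 h (0.0228; 0.115 with an estimated correlation), with COR15A (-1.22) and COR15B (-1.04) called and 3 adjusted over the list alone. HSP23.5-MITO (0.66; list 0.350, 2 adjusted over the list alone) and PIF7 (0.88; list 0.801, 1 higher and 2 lower adjusted over the list alone) were also higher at 24 h. No member of the 4 lists was called at 0 h (camera adjusted p = 0.349 for heat shock, 0.311 for ER folding, 0.418 for thermomorphogenesis and 0.538 for cold) or 96 h (0.641, 0.138, 0.641 and 0.138; 2 cold genes lower adjusted over the list alone). The counts were 32 higher and 30 lower at 0 h, 1163 and 732 at 24 h (963 and 1333 with each array centred), and 212 and 100 at 96 h, with 16 higher and 8 lower at all 3 times. The differences correlated with gene length at 0.429, 0.508 and -0.0299. The count of 62 at 0 h fell to 30 and 31 without the pad4-1 replicates 2 and 3 and 33 and 34 without the SUMO line replicates 2 and 3, that of 1895 at 24 h to 1121 and 1148 without the pad4-1 replicates 1 and 3 and 1051, 1072 and 1162 without the SUMO line replicates 1, 2 and 3, and that of 312 at 96 h to 205 without the pad4-1 replicate 3.

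Both SUMO-deficient lines were then set side by side. Their differences from pad4-1 correlated across genes at 0.716, 0.876 and 0.625 at 0 h, 24 h and 96 h, against 0.50 simulated for unchanged groups sharing 3 control arrays. The simulation drew noise independently for each gene and left out array-wide trends such as that on gene length. What unchanged groups give with such trends is not known. Shared genes numbered 21 higher and 21 lower at 0 h (0.367 and 0.358 for unrelated lists), 1042 and 620 at 24 h (122 and 75.1), and 145 and 66 at 96 h (7.91 and 2.94), with 2, 1 and 4 genes opposite. Both lines share their control arrays, which alone raises overlap and correlation. At 96 h the correlation was 0.425 without the SUMO line replicate 1 and 0.755 without its replicate 2. Tested directly against siz1-2 pad4-1, the SUMO line had QQS higher by 3.21 (SE 0.420, limma adjusted p = 2.80e-05), 3.31 and 2.83 at the 3 times and AT1G36675 higher by 2.61, 2.83 and 2.96. AT2G11405 lay at -4.05, -3.93 and -3.86 and AT1G47740 at -2.24, -2.75 and -2.44. At 96 h QQS and AT1G47740 each lost their call in 1 alternative (limma adjusted p = 0.0753 and 0.0841). Cold genes lay higher in the SUMO line at 0 h (camera adjusted p = 4.67e-11; 6.91e-05 with an estimated correlation), with COR15A called and 4 of 6 adjusted over the list alone. The other lists had no called member, with camera adjusted p = 0.498 for heat shock, ER folding and thermomorphogenesis at 0 h. At 24 h heat shock gave 0.198 and the other lists 0.665, and at 96 h heat shock gave 0.953, ER folding 0.823, thermomorphogenesis 0.408 and cold 0.408. Adjusted over the list alone, 1 thermomorphogenesis gene was higher at 0 h and at 24 h, and 2 were higher and 1 lower at 96 h, when 3 cold genes were higher and 1 lower. The direct comparison called 10 genes higher and 13 lower at 0 h, 15 and 14 at 24 h, and 38 and 41 at 96 h (79 and 40 with each array centred). The differences correlated with gene length at 0.00772, -0.246 and -0.477. The 23 genes at 0 h became 14 without the siz1-2 pad4-1 replicate 3 and 12 without the SUMO line replicate 2, the 29 at 24 h 15 and 18 without replicate 1 of either line, and the 79 at 96 h 34, 31 and 28 without the siz1-2 pad4-1 replicates 1, 2 and 3, 25 without the SUMO line replicate 2 and 1293 without its replicate 1.

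Comparing eTK with pad4-1 asked what the loss of the 3 heat shock factors changes, but the 9 eTK arrays may also form a batch of their own. Such a batch cannot be told apart from the line. The eTK label does not list pad4-1, so PAD4 state and line background may differ too, here and in the eTK interactions. Neither can be told apart from the loss of the factors. At 0 h AT4G19240 stood at 7.47 ± 0.09 against 1.37 ± 0.08 (6.10, SE 0.185, limma adjusted p = 5.38e-22, n = 3), AT5G15360 at 4.12 and AT5G32460 at 3.66 above pad4-1. AT4G05631 (-6.93), AT1G76960 (-5.71) and AT5G28919 (-5.40) were lower, as was the light-harvesting gene LHCB4.2 (AT3G08940) at -4.97, while its near-identical copy LHCB4.1 (AT5G01530) differed by -0.22. At 24 h AT4G19240 (5.21) and AT5G15360 (3.92) were highest and AT1G76960 (-6.10) and AT4G05631 (-5.39) lowest, and at 96 h OSM34 (9.46), AT5G38910 (8.95), LHCB4.2 (-6.66) and AT1G76960 (-6.35). Heat shock genes shifted downward at 24 h (camera adjusted p = 0.00181; 0.00761 with an estimated correlation), with ROF2 (-1.46), HSP15.7 (-1.19), HSP23.5-MITO (-0.94) and FES1A (AT3G09350, -0.64) called among 12. At 0 h HSP17.6A-CI (-1.04) was the 1 called heat shock gene (0.284), and at 96 h 6 were higher and 1 lower (0.0716). ER folding genes gave 0.435 at 0 h, 0.0247 upward at 24 h (0.0350 with an estimated correlation; CRT1b called at 0.69, 2 adjusted over the list alone) and 0.00525 upward at 96 h (0.0127), when all 5 were higher. Their 24 h call was lost without the dimmest probe sets (camera adjusted p = 0.0667). Thermomorphogenesis genes gave 0.350 (2 lower adjusted over the list alone), 0.362 (EXPA8 and IAA29 lower, ARL higher) and, downward, 0.00818 at 96 h (0.0147), with EXPA8 at -6.15 and IAA29 at -4.41. Cold genes gave 0.0694 (KIN2 called at -0.99), 0.572 (COR47 at 0.59) and 0.227. The counts were 557 higher and 618 lower at 0 h, 1029 and 691 at 24 h (744 and 984 with each array centred), and 4615 and 3936 at 96 h (4040 and 5240, with the median over all genes moving from -0.0451 to -0.194), and 147 were higher and 256 lower at all 3 times. The differences correlated with gene length at 0.416, 0.407 and 0.255. The count of 1175 at 0 h fell to 494 and 724 without the pad4-1 replicates 2 and 3 and 661 and 624 without the eTK replicates 1 and 2, and that of 1720 at 24 h to 1014 and 1120 without the eTK replicates 1 and 2.

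The interactions tested whether the responses themselves differed from that of pad4-1. At 96 h AT4G22490, AT4G29030, DFR and PYK10 fell in pad4-1 and fell less or not at all in both SUMO-deficient lines. The interaction was 5.18 and 5.17 for AT4G22490 (limma adjusted p = 1.67e-14 and 1.71e-14) and 4.11 and 3.87 for AT4G29030, in siz1-2 pad4-1 and the SUMO line. It was 3.99 and 2.95 for DFR and 3.21 and 2.86 for PYK10. For AT4G22490, PYK10 and DFR this was not limited to the SUMO-deficient lines. In eTK the AT4G22490 arrays lay from 6.43 to 6.92 at 0 h and from 6.78 to 7.20 at 96 h. PYK10 arrays of both times overlapped there, and DFR fell less than in pad4-1, with its eTK interaction given below. AT2G29920 (-2.30 and -2.39), AT3G22235 (-2.06 and -1.92) and AT2G05915 (-1.98 and -1.31) gave negative interactions in both SUMO-deficient lines, and AT5G26270 (-2.59) in siz1-2 pad4-1. Under some alternatives or left-out arrays these calls were lost, with adjusted p up to 0.152 and 0.174 for AT3G22235 in siz1-2 pad4-1 and the SUMO line, 0.0552 and 0.263 for AT2G29920 and AT2G05915 in the SUMO line and 0.259 for AT5G26270. In siz1-2 pad4-1, 36 interactions were positive and 12 negative at 96 h (28 and 16 with each array centred), in the SUMO line 34 and 6, and 17 positive and 4 negative ones were shared. Both interactions contain the same 6 pad4-1 arrays, which alone raises such overlap. No value for unchanged groups was simulated for them, and across all genes they correlated at 0.551. At 24 h limma called 1 gene in siz1-2 pad4-1, AT2G05540 (-1.64, adjusted p = 3.48e-04), and 0 in the SUMO line, where 1771 and 1238 genes had an unadjusted p under 0.05. Heat shock genes shifted upward in the SUMO line at 24 h (camera adjusted p = 0.0326; 0.0503 with an estimated correlation; no member called, ROF2 at 1.18) and cold genes downward (0.00123; 0.0359; COR15B at -1.02, 2 lower adjusted over the list alone). No other list passed in either line, with camera adjusted p from 0.123 to 0.984 and at most 2 members adjusted over the list alone. The interactions correlated with gene length at 0.424 and 0.0822 in siz1-2 pad4-1 at 24 h and 96 h and at 0.352 and -0.386 in the SUMO line. The count of 48 in siz1-2 pad4-1 rose to 83 without the pad4-1 96 h replicate 2, and that of 40 in the SUMO line became 25 without the pad4-1 0 h replicate 2, 23 without the pad4-1 96 h replicate 3 and 62 without the SUMO line 96 h replicate 1. At 24 h the count of 1 became 2, 17 and 5 without the pad4-1 0 h replicates 1, 2 and 3, 8 without the pad4-1 24 h replicate 3 and 2 without the siz1-2 pad4-1 24 h replicate 2, and that of 0 became 3, 2 and 3 without the pad4-1 0 h replicates 2 and 3 and the 24 h replicate 3.

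For eTK at 96 h the interaction was 9.30 for OSM34 (limma adjusted p = 1.66e-16), 9.28 for AT5G38910, 8.72 for AT3G02480, 7.55 for the chitinase gene CHI (AT2G43570) and 7.53 for the beta-glucosidase gene BGLU27 (AT3G60120), and -5.80 for EXPA8, -5.72 for AT5G48490, -5.59 for AT5G57760 and -5.10 for IQD21 (AT3G49260). In all, 3521 interactions were positive and 2989 negative at 96 h, 2661 and 2065 of them at least 2-fold. With each array centred the median over all genes moved from -0.0485 to -0.159. Heat shock genes shifted upward (camera adjusted p = 0.0192; 0.0305 with an estimated correlation; 6 of 12 positive, HSP17.8 at 3.95), ER folding genes upward (0.00506; 0.0103; 4 of 5, BZIP60 at 3.39) and thermomorphogenesis genes downward (0.00506; 0.0103; 4 of 5, IAA29 at -3.72). Cold genes gave 0.476. These counts were the same adjusted over the list alone. At 24 h 62 interactions were positive and 25 negative (43 and 29 with each array centred), led by AT1G44130 (3.30), AT5G19240 (3.19), AT3G49300 (-2.28) and AT5G26270 (-2.27). The call of AT5G26270 was lost when any 1 of 9 of the 12 arrays was left out (adjusted p up to 0.301). ARL gave 1.28 (list 0.584; 1 higher and 1 lower adjusted over the list alone), heat shock genes 0.0740 (2 lower adjusted over the list alone, ROF2 at -1.47), and ER folding and cold genes 0.0927 each (1 cold gene higher adjusted over the list alone). The interaction correlated with gene length at 0.00581 at 24 h and 0.138 at 96 h. The 24 h count of 87 fell to 40, 49 and 57 without the pad4-1 0 h replicate 2 and 24 h replicates 2 and 3, 44 and 54 without the eTK 0 h replicates 1 and 2, and 57 and 40 without the eTK 24 h replicates 2 and 3.

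Members of the lists too small to test were followed through the responses of all lines, and all their called changes over time are given here or above. Of the flavonoid and anthocyanin genes, DFR was lower after 24 h and 96 h in pad4-1 (-2.16 and -4.97), in the SUMO line (-1.25 and -2.01) and in eTK (-3.11 and -2.61), and at 96 h in siz1-2 pad4-1 (-0.98). The anthocyanin sugar transferase genes UF3GT (AT5G54060, -1.51 and -1.97) and AT4G14090 (-1.69 at 96 h) fell in pad4-1 too. In eTK UF3GT (-1.14 and -1.03) and AT4G14090 (-1.22 and -1.69) fell at both times. PDF1.2 of the jasmonate-ethylene defence list was lower in the 3 lines carrying pad4-1 at both times, while in eTK it lay at -0.79 and 0.19, with an interaction of 2.35 called at 96 h. LHCB4.1 and LHCB4.2 (light harvesting) fell in eTK at 96 h (-2.08 and -1.53), after a rise of LHCB4.2 at 24 h (0.49), as did the aliphatic glucosinolate gene AT2G31790 (-2.28). The replication gene PRL (AT4G02060, an MCM7 helicase subunit) fell at 96 h in pad4-1 (-1.07), the SUMO line (-1.35) and eTK (-2.98, after -1.49 at 24 h). The mitotic Aurora kinases AUR1 (AT4G32830) and AUR2 (AT2G25880) fell in pad4-1 (-1.04 for AUR1) and eTK (-2.42 and -0.94) at 96 h and lay above pad4-1 then in siz1-2 pad4-1 (1.53 and 1.45) and the SUMO line (1.02 and 0.99), although their interactions were called there only when adjusted over the list alone (both genes in both lines). The clock gene GI (AT1G22770) fell in the SUMO line at 96 h (-1.51). The flowering gene AGL24 (AT4G24540) rose there at 24 h and 96 h (0.61 and 0.84) and in siz1-2 pad4-1 at 96 h (0.80). It rose at 24 h (0.63) and fell at 96 h (-0.95) in eTK. SIM (AT5G04470, DNA damage response list) rose in siz1-2 pad4-1 (0.62) and fell in eTK (-1.21) at 96 h. GRX480 had risen in eTK at 24 h (1.56). In the SUMO pathway list, SIZ1 (AT5G60410) fell at 96 h in pad4-1 (-0.53) and the SUMO line (-0.52) and rose in eTK (0.61). AT1G09730 fell at 96 h in pad4-1 (-0.73) and the SUMO line (-0.86). SAE1A (AT4G24940, within 0.29) and AT4G33620 were not called anywhere. Among markers of other organs, the stem cell peptide gene CLV3 (AT2G27250) of the shoot meristem was not called in any comparison (-0.13 to 0.22), and of the root expansins EXPA7 (AT1G12560) was called once (-0.47, eTK against pad4-1 at 96 h) and EXPA18 (AT1G62980) never.

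Between the lines the same small lists held these further calls. Against pad4-1 at 24 h, siz1-2 pad4-1 had GI (1.01), PRL (1.33) and AT2G31790 (0.80) higher, and the SUMO line PRL (0.96), AT2G31790 (0.78), AT1G09730 (0.56) and DFR (0.90). At 96 h AT4G14090 (0.82 and 1.53) and DFR (3.28 and 2.95) were higher in siz1-2 pad4-1 and the SUMO line, PDF1.2 (2.79) in the SUMO line, and GRX480 (-0.69) was lower in siz1-2 pad4-1. AGL24 was lower at 0 h and 24 h in siz1-2 pad4-1 (-0.74 and -0.80) and the SUMO line (-0.73 and -0.56), with a positive interaction in the latter at 96 h (0.92). In eTK PRL (1.03) was higher and PDF1.2 (-1.64) lower than in pad4-1 at 0 h. At 24 h GRX480 (1.77) and SAG101 (1.05) were higher and LHCB4.2 (-4.71) and DFR (-1.40) lower. At 96 h UGT76B1 (6.02), SAG29 (4.99), GRX480 (4.23), DFR (1.91), AT1G09730 (1.28), SAG101 (1.26) and GI were higher. LHCB4.1 (-2.43), AT2G31790 (-1.48), AUR1 (-1.08), AGL24 (-0.98), SIM (-0.96) and PRL (-0.88) were lower. The eTK interaction at 96 h was called for UGT76B1 (5.76), SAG29 (5.50), GRX480 (4.25, and 1.79 at 24 h), DFR (2.36), SIZ1 (1.14) and AT1G09730 (0.91). Negative ones were those of LHCB4.1 (-2.22), AT2G31790 (-1.93), PRL (-1.91), LHCB4.2 (-1.69), AUR1 (-1.37), SIM (-1.20) and AGL24 (-0.87).

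SIZ1 was the 1 targeted gene that could be measured. In siz1-2 pad4-1 it differed from pad4-1 by 0.01, 0.35 and 0.65 (called at 96 h), in the SUMO line by 0.58, 0.96 (called) and 0.59, and in eTK by 0.33, 0.34 and 1.47 (called). Where its probes lie relative to the siz1-2 insertion is not known, so these values do not test the genotype.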

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

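The test of a mislabelled sample was chosen after the results had been seen and the removal of the gene length trend after the arrays had been seen to differ in it, while the interactions and the regroupings of arrays were fixed before. The results here stand out because the response of a line after the move differed from that of pad4-1 in a test of the difference itself (the limma interaction). For each interaction 100 splits were drawn that mix the times within each line. Most splits that gave as many genes as the real one set late arrays of 1 line against early arrays of the other, which adds both responses in place of subtracting them, so these splits are no measure of chance for an interaction and nothing below rests on them.

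At 96 h in eTK the interaction was called for 6510 genes, led by OSM34 (AT4G11650) at 9.30, AT5G38910 at 9.28, AT3G02480 at 8.72 and CHI (AT2G43570) at 7.55, and by EXPA8 (AT2G40610) at -5.80, AT5G48490 at -5.72, AT5G57760 at -5.59 and IQD21 (AT3G49260) at -5.10. A swap of the 3 arrays with pad4-1 arrays is argued against. Of 187 genes at least 2-fold from pad4-1 in eTK at 0 h and 24 h, a share of 0.829 lay on the same side of pad4-1 at 96 h with no overlap of arrays, against 31.4% of the other genes. A wrong time or condition label within eTK would keep such differences, so it stays open. The gene length trend as the whole source is argued against too, because removing it left 1.03 times as many genes called between 96 h and 0 h in eTK, with 7360 of 7506 called in both. Arrays of a batch of their own could add to the differences from pad4-1, but the change within eTK lies inside that batch; whether its 96 h arrays were handled apart is not known. Loss of the heat shock factors, and a state of the plants such as stress or death of leaf tissue at 96 h, stay open. So do PAD4 state and line background, since the eTK label does not list pad4-1. None of these was tested.

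Of the 100 splits 5 gave as many genes for this interaction, the real one included, and the highest other gave 7399. All 4 others add both responses, so they say nothing on chance.

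In eTK at 24 h the interaction was called for 87 genes, among them AT1G44130 (3.30), AT5G19240 (3.19), AT3G49300 (-2.28) and AT5G26270 (-2.27), and 12 splits gave as many (highest other 3304; 9 of the 11 others add both responses). Without 1 array the count was 40 (pad4-1 0 h replicate 2 or eTK 24 h replicate 3), 44 and 54 (eTK 0 h replicates 1 and 2), 49 and 57 (pad4-1 24 h replicates 2 and 3) or 57 (eTK 24 h replicate 2). AT5G26270 lost its call in 2 alternatives and without each 1 of 9 of 12 arrays (adjusted p up to 0.301), and AT3G49300 in 1 alternative (0.123).

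In siz1-2 pad4-1 at 96 h the interaction was called for 48 genes, among them AT4G22490 (5.18), AT4G29030 (4.11), DFR (AT5G42800, 3.99), PYK10 (AT3G09260, 3.21), AT5G26270 (-2.59), AT2G29920 (-2.30), AT3G22235 (-2.06) and AT2G05915 (-1.98); 10 splits gave as many (highest other 3258; 8 of the 9 others add both responses), and the count was 83 without the pad4-1 96 h replicate 2. AT5G26270 lost its call in 2 alternatives and without 1 array (adjusted p up to 0.259) and AT3G22235 in 1 and without 1 (0.152). In the SUMO line at 96 h it was called for 40 genes, among them AT4G22490 (5.17), AT4G29030 (3.87), AT5G33370 (3.18), AT4G22520 (3.11), AT2G29920 (-2.39), AT3G22235 (-1.92), AT2G05915 (-1.31) and AT1G48900 (-1.25); 14 splits gave as many (highest other 5238; 11 of the 13 others add both responses), and the count was 25 and 23 without the pad4-1 0 h replicate 2 and 96 h replicate 3 and 62 without the SUMO line 96 h replicate 1. AT1G48900 lost its call in 4 alternatives and without each 1 of 9 of 12 arrays (adjusted p up to 0.395), AT3G22235 in 2 and 6 (0.174), AT5G33370 in 2 and 3 (0.534), and AT2G29920 (0.0552) and AT2G05915 (0.263) in 1 alternative each.

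At 24 h the interaction of siz1-2 pad4-1 was called for 1 gene, AT2G05540 (-1.64; lost in 1 alternative, adjusted p = 0.115), and 15 splits gave as many (highest other 1303; 11 of the 14 others add both responses); the count was 2, 17 and 5 without the pad4-1 0 h replicates 1, 2 and 3, 8 without the pad4-1 24 h replicate 3 and 2 without the siz1-2 pad4-1 24 h replicate 2. That of the SUMO line at 24 h was called for 0 genes in limma, with 1238 at an unadjusted p under 0.05, and all 100 splits gave as many by construction (highest other 1679), which tests nothing.

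Probe sets that the annotation gives no gene were outside the comparisons. At 0 h, before warming, 267 of 20904 differed between siz1-2 pad4-1 and pad4-1 (limma adjusted p under 0.05 over these probe sets and the rest), 45 between the SUMO line and pad4-1, and 1088 between eTK and pad4-1; they cannot be named and no explanation was tested.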

How the results depend on the processing

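Removal of the gene length trend was chosen after the arrays had been seen to differ in it. The fit on only the probe sets with a gene length, the base for that removal, was not fixed before either. All other alternatives here were fixed before the files were read. A count of genes is said to move when it changes by more than 1.5 times, and a list when its camera adjusted p crosses 0.05. No named gene, and no list with a call, reversed its direction, but the balance of higher and lower genes did: the larger side changed in 10 of 26 comparisons with each array centred on its median, in 4 after quantile normalization and in up to 6 under the other alternatives. With centring the genes higher and lower became 1092 and 864 (from 800 and 996) in pad4-1 at 96 h, and against pad4-1 1558 and 2755 (from 1839 and 1796) in siz1-2 pad4-1 at 24 h, 502 and 1241 (from 653 and 514) in it at 96 h, 963 and 1333 (from 1163 and 732) in the SUMO line at 24 h and 4040 and 5240 (from 4615 and 3936) in eTK at 96 h; the cause was not tested. Which side holds more genes is therefore not settled there. Over all alternatives and left-out arrays, 336 values of the counts stayed within 1.5 times and 135 moved, of which 82 with 1 array left out. Of the named genes 3321 values kept their call and 120 lost it. The values that stayed include 26 counts and 191 named gene values from the fit on probe sets with a gene length. That fit drops few probe sets, so it could change little. Of the lists 948 values kept their side of 0.05, 18 became weaker and 18 stronger. All 26 counts stayed within 1.5 times without the dimmest 25% of the probe sets and, with ratios from 0.750 to 1.29, with the length trend removed. Which genes were called changed more than their number when the length trend was removed. Of the calls before removal, 1064 of 1681 in pad4-1 at 96 h and 2376 of 3753 in the SUMO line at 96 h were kept. So were 1143 of 1806 between the SUMO line and pad4-1 at 24 h. Other comparisons kept a larger share, such as 7360 of 7506 in eTK at 96 h. Of the counts at least 2-fold apart, 4 moved with the length trend removed: 456 to 283 and 988 to 489 in the responses of pad4-1 and the SUMO line at 96 h, and 955 to 583 and 513 to 275 in siz1-2 pad4-1 and the SUMO line against pad4-1 at 24 h. The 19 counts that do not involve eTK stayed so without the eTK arrays.

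A trend and robust prior in limma gave 3 genes in place of 1 for the interaction of siz1-2 pad4-1 at 24 h and 1 in place of 0 for that of the SUMO line; the cause was not tested. Quantile normalization and centring each array on its median also gave 1 gene for the latter, and centring gave 119 in place of 79 between the SUMO line and siz1-2 pad4-1 at 96 h; the cause was not tested.

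Fitted on only the arrays of the groups compared, which leaves fewer samples to estimate the spread, limma called fewer genes in most comparisons. The response of pad4-1 gave 409 and 165 genes at 24 h and 96 h, that of the SUMO line 1794 at 96 h and that of eTK 1342 at 24 h. Against pad4-1, siz1-2 pad4-1 gave 121 and 351 at 0 h and 96 h, the SUMO line 17 and 54, and eTK 582 and 956 at 0 h and 24 h. The SUMO line against siz1-2 pad4-1 gave 12 and 8 at 24 h and 96 h. The interactions gave 0 and 26 in siz1-2 pad4-1 at 24 h and 96 h, 8 in the SUMO line at 96 h and 18 in eTK at 24 h.

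With array weights in limma most counts rose; the cause was not tested, although the weights ran from 0.274 for the SUMO line 96 h replicate 2 to 4.22 for its replicate 3. The responses gave 802 and 2313 genes in siz1-2 pad4-1 at 24 h and 96 h and 777 in the SUMO line at 24 h. Against pad4-1, siz1-2 pad4-1 gave 823 at 0 h and the SUMO line 169 and 652 at 0 h and 96 h. The SUMO line against siz1-2 pad4-1 gave 76, 79 and 2476 at 0 h, 24 h and 96 h. The interactions gave 93 in siz1-2 pad4-1 at 24 h, 1 and 88 in the SUMO line at 24 h and 96 h, and 153 in eTK at 24 h.

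With all probe sets of the table tested, more than 2 times as many, most counts rose by construction. The responses gave 2608 and 3033 in pad4-1, 690 in siz1-2 pad4-1 at 24 h, 811 and 7459 in the SUMO line, and 4508 and 16123 in eTK. Against pad4-1, siz1-2 pad4-1 gave 6495 and 1819 at 24 h and 96 h, the SUMO line 3208 and 526, and eTK 2085, 3025 and 17481 at 0 h, 24 h and 96 h. The SUMO line against siz1-2 pad4-1 gave 45 at 0 h. The interactions gave 64 in the SUMO line at 96 h and 132 and 12703 in eTK.

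With the replicate number as a block, the interaction of siz1-2 pad4-1 at 24 h gave 9 genes, and cold genes between eTK and pad4-1 at 0 h passed (mean -0.38, camera adjusted p = 0.0479); the cause was not tested. Whether equal replicate numbers mark material grown together is not known.

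With 1 array left out, which leaves fewer samples, counts of the responses in limma ranged as follows. In pad4-1 they ran from 584 to 1368 at 24 h and from 627 to 2708 at 96 h, in siz1-2 pad4-1 from 135 to 165 and from 216 to 680, in the SUMO line from 167 to 209 and from 1937 to 4802, and in eTK from 1267 to 2491 and from 7464 to 7614. The arrays behind each move of a count are named with their values in the report.

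Against pad4-1 the counts with 1 array left out ran from 170 to 669, 2341 to 3331 and 481 to 2173 in siz1-2 pad4-1 at 0 h, 24 h and 96 h, from 30 to 89, 1051 to 1547 and 205 to 384 in the SUMO line, and from 494 to 1527, 1014 to 1836 and 7843 to 8397 in eTK. The SUMO line against siz1-2 pad4-1 ran from 12 to 28, 15 to 25 and 25 to 1293. The interactions at 24 h and 96 h ran from 1 to 17 and 34 to 83 in siz1-2 pad4-1, from 0 to 3 and 23 to 62 in the SUMO line, and from 40 to 114 and 6131 to 6469 in eTK.

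Calls of some named genes ended. With the numbers of alternatives and of left-out arrays and the highest adjusted p, these were AT5G33370 (6, 9, 0.405) in the 96 h interaction of siz1-2 pad4-1, AT4G01335 (6, 9, 0.483), AT1G48900 (4, 9, 0.395), AT3G22235 (2, 6, 0.174) and AT5G33370 (2, 3, 0.534) in that of the SUMO line, and AT5G26270 (2, 9, 0.301) in the 24 h interaction of eTK. CML41 (AT3G50770; 1, 4, 0.179) lost it in siz1-2 pad4-1 at 24 h and PDF1.2b (AT2G26020; 0, 4, 0.141) in the SUMO line at 24 h. Between the SUMO line and pad4-1 at 0 h NAI2 (AT3G15950; 1, 4, 0.241), AT4G36100 (2, 4, 0.195), AT3G23550 (1, 3, 0.144) and AT2G40955 (1, 2, 0.263) lost it. Between siz1-2 pad4-1 and pad4-1 at 0 h AT1G73325 (0, 3, 0.0655), AT2G40955 (1, 0, 0.126) and QQS (AT3G30720; 1, 0, 0.0814) lost it. So did QQS (1, 1, 0.0936) and AT5G26270 (1, 0, 0.0525) in pad4-1 at 24 h, AT5G26270 (1, 0, 0.0619) in it at 96 h, AT4G17470 (0, 2, 0.103) and AT4G22485 (0, 2, 0.0648) in siz1-2 pad4-1 at 24 h and 96 h, and QQS (1, 0, 0.0753) and AT1G47740 (1, 0, 0.0841) between the SUMO line and siz1-2 pad4-1 at 96 h. In the 96 h interaction of siz1-2 pad4-1 AT5G26270 (2, 1, 0.259), AT3G22235 (1, 1, 0.152), AT1G06100 (1, 0, 0.0575) and AT4G18250 (1, 0, 0.0639) lost it, in that of the SUMO line AT2G29920 (1, 0, 0.0552) and AT2G05915 (1, 0, 0.263), and at 24 h AT2G05540 (1, 0, 0.115) in siz1-2 pad4-1 and AT3G49300 (1, 0, 0.123) in eTK. The cause was not tested.

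The correlation of both SUMO-deficient lines' differences from pad4-1 ran from 0.630 to 0.798 at 0 h, 0.844 to 0.884 at 24 h and 0.425 to 0.755 at 96 h with 1 array left out. It was 0.736, 0.891 and 0.624 without the dimmest probe sets, 0.715, 0.876 and 0.630 after quantile normalization, and 0.696, 0.848 and 0.653 with the length trend removed.

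Of the lists, ER folding and cold genes between siz1-2 pad4-1 and pad4-1 at 24 h lost their call in camera under several alternatives. Without the dimmest probe sets they gave means of 0.50 and -0.56 (adjusted p = 0.0748), after quantile normalization 0.45 and -0.54 (0.0587) and with the length trend removed 0.41 and -0.42 (0.0810). With an estimated correlation ER folding genes gave 0.50 (0.0807) and cold genes -0.56 (0.160). The cause was not tested. The same lists in the SUMO line gave 0.42 and -0.49 (0.0528) without the dimmest probe sets, and 0.42 (0.0650) and -0.49 (0.115) with an estimated correlation; the cause was not tested.

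The estimated correlation also took the camera call from cold genes at 96 h in the response of siz1-2 pad4-1 (0.44, 0.103) and in its difference from pad4-1 (-0.54, 0.150), and from heat shock genes in the 24 h interaction of the SUMO line (0.30, 0.0503); the cause was not tested. Without the dimmest probe sets ER folding genes of eTK against pad4-1 at 24 h gave 0.43 (0.0667), while heat shock genes passed in the 24 h interaction of eTK (-0.36, 0.0258). With all probe sets of each list gene, which tests more probe sets, ER folding genes passed between siz1-2 pad4-1 and pad4-1 at 0 h (0.24, 0.0491) and heat shock genes between eTK and pad4-1 at 96 h (0.77, 0.0325). With the length trend removed ER folding (0.41) and thermomorphogenesis genes (-0.48) passed in eTK at 24 h (0.0355). The cause was not tested.

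With 1 array left out, camera calls of these lists crossed 0.05. Cold genes of siz1-2 pad4-1 against pad4-1 at 96 h ran from -0.60 to -0.47 (0.0217 to 0.0666; -0.54 and 0.0345 with all arrays). ER folding genes at 0 h ran from 0.15 to 0.29 (0.0430 to 0.247; 0.24 and 0.0702). Cold genes of eTK against pad4-1 at 0 h ran from -0.50 to -0.29 (0.0216 to 0.257; -0.38 and 0.0694). In eTK at 24 h ER folding genes ran from 0.36 to 0.42 and thermomorphogenesis genes from -0.48 to -0.37 (0.0446 to 0.202; 0.39, -0.43 and 0.0696). In the 96 h interaction of the SUMO line cold genes ran from -0.48 to -0.12 (0.00750 to 0.441; -0.32 and 0.123) and heat shock genes from 0.0932 to 0.276 (0.0456 to 0.695; 0.18 and 0.300).

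Background values were not used here, so how far a signal stood above background is not known, and genes such as AT4G22490 in pad4-1 at 96 h (1.15) lay near the lowest values, where the size of a difference is least certain.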

Other observations

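The ribosome biogenesis, ER body and iron lists and the neighbour test were chosen after leading genes had been seen, while the regroupings of arrays were fixed before. Genes of ribosome biogenesis fell in pad4-1 at 24 h, with 28 of 30 lower (median -1.38; limma camera adjusted p = 3.82e-41, 2.85e-04 with an estimated correlation), among them NOP58-1 (AT5G27120, -2.16), UTP10 (AT3G06530, -2.13) and UTP12 (AT3G21540, -1.67). Some of the 30 had been seen to fall before the list was made, so these p values are no independent support. At 24 h 11 fell in siz1-2 pad4-1, 13 in the SUMO line and 27 in eTK. Such counts do not test whether the responses differed, and no interaction of this list is given here. Over all genes the 24 h interaction called 1 gene in siz1-2 pad4-1 and 0 in the SUMO line. In siz1-2 pad4-1 20 of 30 lay above pad4-1 then (camera adjusted p = 1.53e-14; 0.0187) and in the SUMO line 18. These comparisons reuse the pad4-1 24 h arrays in which the fall had been seen. The length trend was not removed for them, and the siz1-2 pad4-1 difference correlated with gene length at 0.502. At 96 h 19, 12 and 19 were lower in pad4-1, siz1-2 pad4-1 and the SUMO line, while in eTK 4 rose and 7 fell (0.418). Of 6 iron deficiency genes IMA1 (3.01), IMA2 (2.35) and BHLH101 rose in pad4-1 at 96 h and prompted the list, so no list test is given. Of the 3 others PYE (1.15) rose, and BTSL1 (0.16) and KELCH (0.04) were not called.

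Families of genes sharing a symbol stem, added before any difference was computed, moved in eTK at 96 h. All 10 autophagy genes (ATG8 and ATG3) rose (median 2.28; camera adjusted p = 1.75e-06, but 0.0787 with an estimated correlation). Of 24 plastid expression genes 22 fell (1.06e-07; 0.0787), as did 9 of 10 ndh genes (3.01e-05; 0.154), 11 of 17 IQD genes (1.66e-04; 0.0787), 8 of 22 expansins (0.0181; 0.0787) and 11 of 23 TBL genes (0.0262; 0.0787). In pad4-1 at 24 h 4 of the 10 autophagy genes rose (7.31e-05; 0.247). Of the pad4-1 response at 24 h, 279 higher and 364 lower genes were shared with eTK (41.2 and 32.5 by chance) and 6 went opposite ways. At 96 h 229 and 511 were shared (193 and 214 by chance), 396 went opposite ways, and the correlation across all genes was 0.146 (0.535 at 24 h). In all 4 lines 22 and 65 were shared at 24 h and 41 and 94 at 96 h.

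The fall of ribosome biogenesis genes led to the prediction that members not yet seen would fall beyond the gene length trend. With that trend removed the unseen members gave camera adjusted p = 1.14e-23 at the preset correlation (1 set tested), downward, so the prediction was met. They were measured on the same arrays in which the fall had been seen, so this is no independent support. Their value with an estimated correlation is not given here, and for the whole list that setting raised p by far, as given above. For ER body genes the prediction was that unseen members would fall less in both SUMO-deficient lines at 96 h. The 6 unseen members gave 0.122, so it was not met, and 6 members are too few to show that nothing differed. The level against pad4-1 was another matter, although 5 of the 11 genes had prompted the list. At 0 h 3 of all 11 ER body genes were already higher in siz1-2 pad4-1 (camera adjusted p = 1.46e-05; 0.00172 with an estimated correlation) and 3 in the SUMO line (4.19e-07; 2.52e-04), and at 24 h 5 and 6. These values include the genes that prompted the list, so they are no independent support. Values of the unseen members alone are given here for 96 h only. At 96 h 8 of 11 lay above pad4-1 in siz1-2 pad4-1 (camera adjusted p = 3.62e-14; 1.11e-06 with an estimated correlation) and 8 in the SUMO line (1.27e-21; 2.18e-08). The unseen members alone gave adjusted p = 0.00530 (0.0105) and 5.09e-05 (4.80e-04), 1 set tested, for that difference, which was not what had been predicted. They too were measured on the arrays in which the leading genes had been seen. JAL22 and JAL23 were first counted as unseen by mistake, and with them the prediction had been met.

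The 3635 genes between siz1-2 pad4-1 and pad4-1 at 24 h were weighed because the difference followed gene length. With the length trend removed 2770 genes were called in place of 3415 (0.811), but only 2273 of them in both fits. Without the siz1-2 pad4-1 replicate 1 the count was 2341 (0.644), so neither explains the whole. A part could come from either. Loss of SIZ1 stays open, and what gives rise to the trend was not tested.

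Of the genes that differed between eTK and pad4-1 alike at all 3 times, 52.3% had another 4 to 15 genes away on the chromosome, against 42.0% on average, 47.5% at the 95th percentile and 52.6% at most in 1000 random draws, 2 of which were as high. A strain variant or introgressed segment and a difference between array batches cannot be told apart by this, since the limit set before was above all draws. Leading temperature genes gave 47.4% and the genes constant in siz1-2 pad4-1 20%, where random draws gave 18.0%. Loss of the heat shock factors stays open too, as does PAD4 state, since the eTK label does not list pad4-1.

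Each set of 6 arrays can be regrouped in 10 ways, too few splits for a share under 0.05, and in all but 1 comparison only the real split, 1 of 10, gave as many genes. Real and highest other counts of the responses at 24 h and 96 h were 1153 and 2, then 1796 and 648 in pad4-1; 292 and 0, then 819 and 1 in siz1-2 pad4-1; 352 and 0, then 3989 and 6 in the SUMO line; and 2283 and 9, then 7971 and 1 in eTK. Against pad4-1 at 0 h, 24 h and 96 h they were 410 and 2, 3635 and 2, and 1167 and 1 for siz1-2 pad4-1, 62 and 2, and 1895 and 0 for the SUMO line at 0 h and 24 h, and 1175 and 1, 1720 and 0, and 8551 and 4 for eTK. The SUMO line against siz1-2 pad4-1 gave 23 and 1, 29 and 0, and 79 and 1. For the SUMO line against pad4-1 at 96 h, 2 of 10 splits gave as many: 312 for the real one and 1291 for another. The latter set replicates 1 and 3 of the SUMO line with replicate 2 of pad4-1 against the rest. It sorts the arrays by slope on gene length, with -0.35, -0.83 and -0.40 against -1.56 (SUMO line replicate 2), -1.01 and -1.08 (pad4-1 replicates 1 and 3). The split with 648 genes in pad4-1 sorts its arrays by this slope too. So a grouping along the length trend called more genes here than the line did. Whether the trend alone gives these calls was not tested.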
